A study of Rattus norvegicus with 15 samples.

How the data were processed

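The series holds 15 arrays of RNA from hearts of male Sprague-Dawley rats, 5 each from sham-operated animals and from animals killed 12 h and 24 h after induction of severe acute pancreatitis, per the labels. The groups were taken from the sample titles and source names. The labels do not agree in every field: the series title and an RNA extraction note speak of ischemia/reperfusion, and that note also names mice and other hours, whereas every sample's source name, description and treatment protocol give pancreatitis or sham surgery in rats. The design text names a mouse array, while the probe set identifiers and the platform table are those of a rat transcript-cluster array. The sample-level fields were followed. Per the design text the hearts numbered 5 per group; the labels name no litter, batch, slide or scan day, so no batch could be tested.

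The deposited values are log2 expression values per transcript cluster that the authors normalized together, given to 2 decimals. Per the submitters' processing notes Affymetrix Expression Console was used (its version is not given in the sources used here), and the deposited table is named as RMA output, a method of background correction, quantile normalization and median polish. That the scale is log2 rests on this name. The range of the values, from 2.51 to 19.83, does not settle the scale or the variant of the method. The fold sizes given here hold only if the values are plain log2. A second deposited table held the same values, with a largest difference of 0. There were 23188 probe sets, no control probe sets and no missing values. Through GEO's platform annotation 15049 probe sets had 1 gene symbol, 0 had several and 8139 are unnamed here. Updating the symbols through the gene IDs changed 0 of them. Of 15037 distinct symbols 10 had 2 or more probe sets, and the probe set with the highest mean over all arrays stood for the gene. Depth has no counterpart on arrays, so the number of arrays limits the precision. The median standard error of a log2 fold change was 0.150. As a guide to background, the 13 measured pancreatic acinar genes had a median level of 4.65 log2 and the 10 skeletal muscle genes 4.59, and 50.7% of probe sets had a mean under 6.

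Group means were fitted to all 15 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, so that the 3 comparisons shared 1 estimate of the spread, and p-values were adjusted over the 23188 probe sets by the Benjamini-Hochberg method; a probe set with adjusted p under 0.05 was called. No probe set was filtered and no fold change threshold was set. Fold changes are log2 differences with limma's standard error. Fixed gene lists, 44 in number with 627 of 699 listed genes measured, covered inflammation, stress, metabolism, contraction, matrix and markers of cell types that a heart sample can hold. They were tested with camera at a preset correlation of 0.01, adjusted over the 44 lists per comparison; camera with an estimated correlation and fry were the alternatives, and a list needed 5 measured members. Members were also counted with p adjusted over the list alone.

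The genes named in the text followed a rule that, like the groups, comparisons, tests, gene lists and alternatives, was fixed before the data were examined. For each comparison with sham these were the 10 largest rises and the 10 largest falls among named genes with adjusted p under 0.05 and no overlap between the arrays of both groups, for 24 h against 12 h the 5 largest of each, and in addition up to 4 members with the smallest adjusted p of each list called by camera, of which a part is given. Some genes outside the rule are also given and not always marked as such, among them Per2, Per3, Tef, Csf3r, Cxcr2, Adipoq and Myl2. For cell type lists that moved, levels of their members were also looked at.

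The alternatives were centring each array on its median, quantile normalization repeated, leaving out the lowest 25% or 50% of probe sets by mean, eBayes with trend and robust settings, array weights, fitting only the compared groups, the replicate number as a block, leaving out each array in turn, adjusted p under 0.01, a 2-fold minimum, genes in place of probe sets, and the mean of all probe sets per gene. After the data were seen, 2 more were added because atrial transcripts varied between arrays: the mean of 6 atrial markers (Nppa, Myl7, Myl4, Sln, Bmp10 and Stard10) as a covariate, and the fit without the 4 arrays in which Myl4 and Sln both exceeded 12 log2. The fit without the 4 arrays has fewer sham and 12 h arrays, so it can also lose calls through lower power. For each comparison 100 of the 126 splits of its 10 arrays into groups of 5 were refitted.

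The fit was tested on simulated data with the real means and residual spreads, in which 200 of 23188 probe sets were changed. For 12 h against sham it recovered 42% of probe sets changed by 0.5 log2, 88% of those changed by 1, 98% of those changed by 2 and 100% of those changed by 3. For 24 h against sham these shares were 28%, 88%, 100% and 98%, and for 24 h against 12 h 26%, 86%, 98% and 100%. False calls numbered 5, 1 and 12. Camera called the 1 shifted list in each simulated comparison and 0 others. The simulated probe sets were drawn independently of each other, so this does not show how often camera calls lists of correlated genes. Tables were read with Python 3.11.15 and pandas 2.3.3, and matplotlib 3.10.9 drew the figures.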

Results

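Gene expression was measured in heart RNA of male Sprague-Dawley rats with severe acute pancreatitis (SAP), an inflammation of the pancreas that was started by infusing 5% sodium taurocholate, a bile salt, backwards into the pancreatic and biliary ducts. Hearts were taken 12 h and 24 h after the infusion. Rats with sham surgery served as controls, and each of the 3 groups held 5 arrays, 15 in all. The arrays gave 23188 probe sets, of which 15049 had 1 gene symbol. Array medians lay between 5.9 and 5.98 on the log2 scale, and the mean correlation of an array with its own group lay between 0.987 and 0.994. The median standard deviation of a probe set within a group was 0.210 log2 in the sham hearts, 0.245 at 12 h and 0.212 at 24 h. The hour of day at which the animals were killed and the time at which the sham hearts were taken are not given in the sources used here.

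The first comparison asked how hearts taken 12 h after SAP was started differed from sham hearts. As no hour of day is given, time of day cannot be told apart from SAP for any gene in the comparisons with sham. The 10 largest rises and falls without overlap between the groups come first. Chi3l1, a chitinase-like glycoprotein, was 17.7-fold higher (log2 fold change 4.14 ± 0.46 SE, adjusted p = 4.87e-05), moving from 6.34 ± 0.48 (SD, n = 5) in sham hearts to 10.48 ± 0.54. S100a9 and S100a8, the subunits of calprotectin, were 9.16-fold and 6.36-fold higher. Lcn2, an iron-siderophore binding protein, was 6.84-fold higher, and Fgg, the fibrinogen gamma chain, 7.81-fold. The other leading rises were Cyp2e1, a cytochrome P450 (10.7-fold), Slc41a3 (8.1-fold), the glutathione transferase Mgst1 (6.29-fold), the ectonucleotidase Enpp3 (4.46-fold) and Ifitm1 (4.3-fold). Mt1, a metal-binding metallothionein, had the largest fall of this kind, 10.2-fold lower (log2 fold change -3.36 ± 0.47 SE, adjusted p = 3.72e-04). The clock output gene Dbp was 8.22-fold lower and the glutamine transporter Slc38a3 8.06-fold lower. Fcer2 was 6.34-fold lower, the NADPH oxidase subunit Ncf1 5.67-fold, the tubulin Tuba4a 4.94-fold, the triglyceride synthesis enzyme Dgat2 4.68-fold and Noct 3.86-fold. Trim16 (log2 fold change -1.90) and the stress transcription factor Atf3 (-1.86) closed the list, and their adjusted p rose to 0.0676 without sham replicate 4 and to 0.0512 without sham replicate 5. For each of these 20 genes every 12 h array lay on one side of every sham array. The sham means of S100a9, S100a8 and Fgg (5.01, 5.17 and 5.49 log2) and the 12 h mean of Fcer2 (4.54) lay near the median of 4.65 of pancreatic acinar genes, a guide to background. The folds of these 4 genes are therefore no exact sizes and can be too small.

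**Figure D1:**
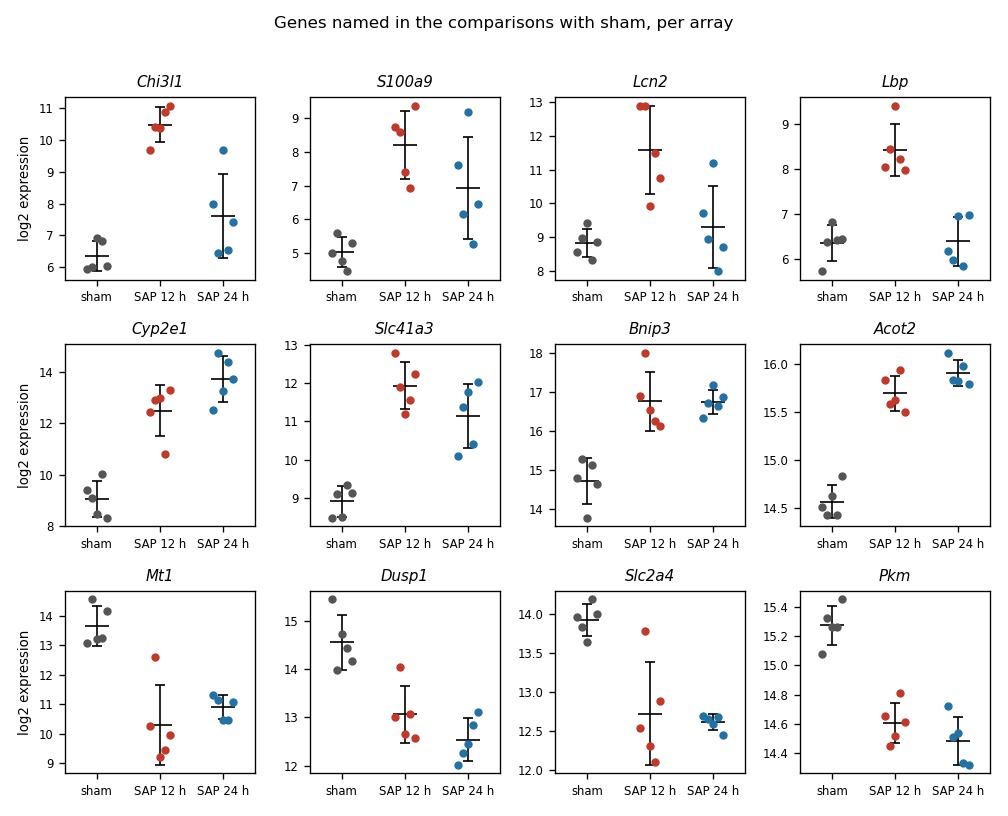
Each panel shows the log2 expression (y axis) of 1 gene in the 5 sham, 5 SAP 12 h and 5 SAP 24 h arrays (x axis, a point per array), with the group mean and its standard deviation as the bar and whiskers; panels have their own y range. Chi3l1 and Lbp are high at 12 h and lower again at 24 h, whereas Cyp2e1, Acot2 and Bnip3 are high at both times.

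Among the gene lists fixed in advance, the acute-phase and complement list had the clearest rise at 12 h. Of its 19 measured members 11 rose and none fell (13 rose and none fell when p was adjusted over the list alone), with a mean log2 fold change of 1.29 (camera adjusted p = 4.24e-11, and 0.0117 with an estimated correlation). The lipopolysaccharide-binding protein Lbp rose by 2.06 log2, the complement protease C1s by 1.51, the oncostatin M receptor Osmr by 1.06 and the metalloproteinase inhibitor Timp1 by 2.08. The largest rise in this list was that of Serpina3n, a serine protease inhibitor (log2 fold change 5.17 ± 1.20 SE, adjusted p = 0.0154). It was singled out after its values were seen, its 12 h and sham arrays overlapped, and its call was lost without the 4 arrays rich in atrial transcripts. None of the 19 members of the list of inflammatory cytokines and NF-kB targets passed limma's test at 12 h, over all probe sets or adjusted over the list alone, and 4 had an unadjusted p under 0.05 (camera adjusted p = 0.0591). Macrophage and monocyte markers were higher in sum, with 5 of 15 called and all 15 positive (11 when adjusted over the list alone; camera adjusted p = 5.07e-09, but 0.129 with an estimated correlation). C1qb rose by 1.25 log2 and Fcer1g by 0.92, and 2 macrophage and monocyte markers were called without the 4 arrays rich in atrial transcripts (list camera adjusted p = 6.60e-06). With the atrial covariate 7 of these markers were called higher. Of 13 neutrophil markers, S100a9, S100a8, Lcn2 and Mmp8 (1.38 log2, from a low sham mean of 4.90) rose (7 when adjusted over the list alone). Camera gave adjusted p = 4.41e-06 for this list, but adjusted p = 0.164 with an estimated correlation. The other 9 neutrophil markers, among them Csf3r and Cxcr2, were not called. The interferon response list went the other way. Usp18 fell by 1.62 log2 and the transcription factor Irf7 by 2.03, 3 of 20 members were called lower (7 when adjusted over the list alone) and none higher. By camera the list had adjusted p = 2.20e-06, and adjusted p = 0.337 with an estimated correlation. The sham arrays differed widely on this list, with a score of 0.91 in replicate 2 and -0.66 in replicate 3, against -1.03 to -0.38 in the 12 h arrays. Its mean was -0.75 log2, but -0.50 with 2 members called lower without the 4 arrays rich in atrial transcripts (camera adjusted p = 0.00387).

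Some genes of protein folding and degradation also rose at 12 h. In the unfolded protein response list 9 of 18 members rose and 1 fell (12 and 2 when adjusted over the list alone). For this list camera adjusted p was 5.75e-07, but adjusted p = 0.129 with an estimated correlation. The endoplasmic reticulum chaperones Pdia4 and Dnajc3 rose by 1.62 and 1.04 log2 and the transcription factor Xbp1 by 0.89, while Ddit3, a stress-induced transcription factor, fell by 1.26. Without the 4 arrays rich in atrial transcripts 2 members rose and 1 fell, and the list stayed called (mean 0.33 log2, camera adjusted p = 3.26e-04). With the atrial covariate 9 members rose and 1 fell. In the list of atrophy, ubiquitin and autophagy genes 4 of 16 rose and none fell (8 rose and 1 fell when adjusted over the list alone). The list had camera adjusted p = 5.20e-05, and adjusted p = 0.212 with an estimated correlation. The mitophagy receptor Bnip3 was 4.11-fold higher, the lysosomal protease Ctsl rose by 1.36 log2 and the autophagosome protein Map1lc3b by 0.91. All 18 measured ribosomal protein genes had positive values but only Rps6 was called (0.47 log2), and its adjusted p was 0.0502 without SAP 12 h replicate 1. As a list the ribosomal proteins had camera adjusted p = 5.75e-07, but adjusted p = 0.322 with an estimated correlation and 0.0635 without the 4 arrays rich in atrial transcripts.

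Some genes of glucose use and of mitochondrial energy metabolism fell at 12 h. Of 21 measured members of the glycolysis and glucose uptake list 8 fell and none rose (9 fell when adjusted over the list alone), with a mean log2 fold change of -0.45 (camera adjusted p = 6.92e-07, and 0.0117 with an estimated correlation). The insulin-responsive glucose transporter Slc2a4 fell by 1.21 log2, the muscle phosphoglycerate mutase Pgam2 by 0.95, the phosphofructokinase Pfkm by 0.80 and the pyruvate kinase Pkm by 0.67. In the oxidative phosphorylation list 5 of 27 fell, among them the cytochrome c1 gene Cyc1 (by 0.80 log2), and none rose (10 fell when adjusted over the list alone). Camera gave adjusted p = 2.29e-08 for this list, but adjusted p = 0.337 with an estimated correlation. In the TCA cycle list 3 of 14 fell, which were Dlst (-0.70 log2), Idh3a (-0.52) and Ogdh (-0.57), and 4 fell when adjusted over the list alone. By camera the list had adjusted p = 0.00218, and adjusted p = 0.430 with an estimated correlation. In the oxidative phosphorylation list 3 members were called without the 4 arrays rich in atrial transcripts, and in the TCA cycle list 0. With the atrial covariate 6 and 3 members of these lists were called lower. The acyl-CoA thioesterase genes Acot1 and Acot2, members of the PPAR target list, rose by 1.13 and 1.13 log2, whereas Dgat2 of the same list fell. In that list 3 of 16 rose and 2 fell (5 and 2 when adjusted over the list alone). Of the contractile and calcium-handling list 2 of 17 were called lower, including the calcium-binding protein Casq2 (-0.71 log2; camera adjusted p = 0.00218; adjusted p = 0.430 with an estimated correlation), and 4 when adjusted over the list alone.

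Genes of the circadian clock moved in both directions at 12 h. Of 14 measured members 3 rose and 5 fell (3 and 9 when adjusted over the list alone). The activators Bmal1 and Clock rose by 1.98 and 1.32 log2, while the output gene Dbp and the repressor Ciart fell by 3.04 and 1.80 (camera adjusted p = 0.00292 for a net fall; adjusted p = 0.322 with an estimated correlation). At 24 h the means of Bmal1, Clock, Dbp and Ciart differed from sham by 0.07, 0.10, -0.05 and -0.19 log2, and limma called no clock gene against sham, while 3 of 14 had an unadjusted p under 0.05. These 3, Per2, Per3 and Tef, had fallen by 1.11, 1.37 and 1.59 log2 at 12 h. At 24 h their values were -0.50, -0.67 and -0.69 (adjusted p = 0.193, 0.155 and 0.249), and the test of 24 h against 12 h did not call them either (adjusted p = 0.172, 0.201 and 0.177).

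**Figure D2:**
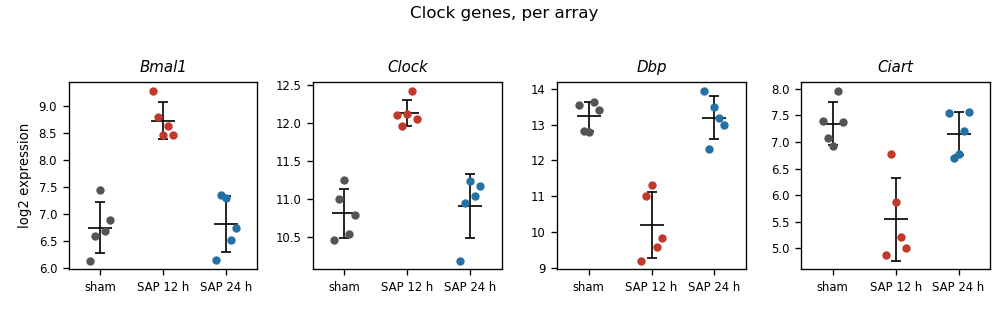
Each panel shows the log2 expression (y axis) of 1 clock gene in the 5 sham, 5 SAP 12 h and 5 SAP 24 h arrays (x axis, a point per array), with the group mean and standard deviation; panels have their own y range. Bmal1 and Clock are higher and Dbp and Ciart lower at 12 h than in both other groups.

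In total limma called 1140 probe sets at 12 h, 544 higher and 596 lower, and 327 of these differed at least 2-fold. Repeated quantile normalization gave 510 higher and 682 lower, and median centring gave 472 and 640. Over all probe sets, called or not, every array of one group lay beyond every array of the other for 1108 (4.78%), where chance gives 0.794%, and 786 of these were called. Camera called 19 of 44 lists, but with an estimated correlation only the acute-phase and the glycolysis lists kept a call. A further 7 called lists each lost the call with 1 array left out, with these highest adjusted p: immediate early (0.147 without SAP 12 h replicate 4), fatty acid oxidation (0.220 without SAP 12 h replicate 4), PPAR targets and lipid handling (0.185 without SAP 12 h replicate 4) and oxidative stress and NRF2 targets (0.138 without SAP 12 h replicate 2). For the remaining lists these were ferroptosis and iron handling (0.0574 without SAP 12 h replicate 4), extracellular matrix (0.152 without sham replicate 3) and matrix remodelling enzymes (0.0787 without SAP 12 h replicate 1). Fry called 14 lists. Of the genes named for this comparison, the calls of Atf3, Dlst, Fcer1g, Fga, Idh3a, Kcnq1, Ogdh, Rps6, Serpina3n, Trim16 and Xbp1 were lost without the 4 arrays rich in atrial transcripts. That fit has fewer sham and 12 h arrays and so less power. None of these calls was lost with the atrial covariate and all arrays. The covariate fit called 1241 probe sets, of which 1109 were also called without the covariate. Without the 4 arrays rich in atrial transcripts, which are described with the 24 h hearts, 598 probe sets and 19 lists were called, and 508 of these probe sets were also called with all arrays. The lists were not the same: 6 lost the call (fatty acid oxidation, PPAR targets, iron handling, immediate early, matrix remodelling and ribosomal proteins). Another 6 gained it, namely inflammatory cytokines and NF-kB targets (camera adjusted p = 0.0146), endothelial activation, cardiac stress, endothelial cells, fibroblasts and atrial markers.

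The second comparison asked what differed from sham 24 h after SAP was started. Cyp2e1 was now 25.4-fold higher (log2 fold change 4.67 ± 0.45 SE, adjusted p = 2.46e-05), from 9.06 ± 0.69 (SD, n = 5) in sham hearts to 13.73 ± 0.89. The other leading rises were Bex1 (9.34-fold), Asb18 (8.62-fold), Pbld1 (5.14-fold), Slc41a3 (4.65-fold), Bnip3 (4.08-fold), the glutathione transferase Gstt2 (4-fold), the fatty acid transporter Slc27a1 (3.28-fold), Tmem71 (3.27-fold) and Cadps (3.26-fold). The metallothioneins Mt1 and Mt2A were 6.71-fold and 5.91-fold lower, Fcer2 6.14-fold (to a mean of 4.59 log2, near background), Doc2g 4.41-fold, Tuba4a 4.18-fold, Ncf1 4.16-fold, the MAP kinase phosphatase Dusp1 4.07-fold, Tsc22d4 3.98-fold and the hexokinase Hk2 3.94-fold. The largest fall of this kind was that of Myl7, the atrial myosin light chain (log2 fold change -7.93 ± 2.00 SE, adjusted p = 0.0354). This call was lost in 8 of the 15 fits that left out 1 array, with adjusted p up to 0.0927 without SAP 24 h replicate 2. For each of these 20 genes the 24 h and sham arrays did not overlap.

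At 24 h some fuel genes were called higher and others lower. In the glycolysis and glucose uptake list 9 of 21 members fell and 1 rose (13 and 1 when adjusted over the list alone), with a mean log2 fold change of -0.55 (camera adjusted p = 1.53e-08, and 0.00461 with an estimated correlation). Hk2 fell by 1.98 log2, Slc2a4 by 1.32, Pkm by 0.79 and Pgam2 by 0.76. In the fatty acid oxidation list 6 of 19 rose and none fell (13 rose when adjusted over the list alone; camera adjusted p = 1.07e-07, but 0.557 with an estimated correlation). The mitochondrial enzymes Ech1 and Eci1 rose by 0.99 and 0.90 log2 and the carnitine palmitoyltransferase Cpt1b by 0.53, and without sham replicate 3 their adjusted p were 0.0606, 0.0640 and 0.0607. Only 1 member of the fatty acid oxidation list rose with the atrial covariate and 0 without the 4 arrays rich in atrial transcripts. The list stayed called in both (mean 0.37 and 0.31 log2, camera adjusted p = 3.95e-06 and 2.20e-04). Of the PPAR targets and lipid handling list 3 of 16 rose, namely Acot2 (1.35 log2), Acot1 (1.28) and Slc27a1 (1.71), and 1 fell (6 and 1 when adjusted over the list alone). For this list camera adjusted p was 0.00911, but adjusted p = 0.557 with an estimated correlation. Catalase (Cat) rose by 0.87 log2 and the thioredoxin inhibitor Txnip by 0.78. They were 2 of 3 called members of the 17 genes of the oxidative stress and NRF2 target list, none of which fell (3 when adjusted over the list alone). This list had camera adjusted p = 0.0212, but adjusted p = 0.557 with an estimated correlation and 0.0847 without sham replicate 3. It also lost the call with the atrial covariate (camera adjusted p = 0.157) and without the 4 arrays rich in atrial transcripts (0.0897). Bnip3 and Map1lc3b (0.81 log2) were among 5 of 16 members of the atrophy, ubiquitin and autophagy list that rose, and none fell (6 when adjusted over the list alone). The list had camera adjusted p = 0.00385, and adjusted p = 0.557 with an estimated correlation.

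Some stress-hormone and stress-response genes were called lower at 24 h. In the glucocorticoid-induced list 4 of 16 fell and none rose (5 when adjusted over the list alone), namely Mt1, Mt2A, Dusp1 and the kinase Sgk1 (-1.22 log2), with camera adjusted p = 0.00100 for the list (adjusted p = 0.557 with an estimated correlation). The Sgk1 call was lost in 11 of the 15 fits that left out 1 array, with adjusted p up to 0.120 without SAP 24 h replicate 4. In the immediate early list Dusp1 and Egr1 fell by 2.02 and 1.87 log2, out of 16 members, and none rose (3 fell when adjusted over the list alone). Camera gave adjusted p = 0.00469 for this list, but adjusted p = 0.557 with an estimated correlation. Of 12 heat shock protein genes 4 fell and none rose (4 and 1 when adjusted over the list alone), among them the chaperones Hspd1 (-0.70 log2) and Hsph1 (-0.64; list camera adjusted p = 0.0163; adjusted p = 0.557 with an estimated correlation and 0.0542 without the 4 arrays rich in atrial transcripts). With the atrial covariate 2 heat shock genes were called lower, and 1 without the 4 arrays. Of the acute-phase list 1 of 19 members, C1s, was called higher, by 1.01 log2 (1 when adjusted over the list alone; camera adjusted p = 0.144). The neutrophil list had camera adjusted p = 0.00173 (0.557 with an estimated correlation) with Mmp8 as its 1 called member (1.05 log2), or 3 called when adjusted over the list alone, and the S100a9 value was 1.91 ± 0.56 (SE, adjusted p = 0.0705). The sham means of Mmp8 and S100a9 (4.90 and 5.01 log2) lay near background, so these values are no exact sizes either.

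The matrix, fibroblast and atrial lists were called lower by camera at 24 h, with few members called by limma. Of 16 extracellular matrix genes 2 fell and none rose (7 and 1 when adjusted over the list alone), the proteoglycan Bgn by 1.72 log2 and the collagen Col1a2 by 1.11, with adjusted p of 0.0579 and 0.104 without sham replicate 3. The matrix list had a mean log2 fold change of -0.72. By camera the list had adjusted p = 0.00100, and adjusted p = 0.557 with an estimated correlation. Of 12 fibroblast markers 1 was called lower (6 when adjusted over the list alone) and the mean was -0.78 log2. For this list camera adjusted p was 7.45e-04, but adjusted p = 0.557 with an estimated correlation. Of the 9 atrial and conduction markers all were negative and Myl7 alone was called (1 when adjusted over the list alone). The list had a mean of -2.58 (camera adjusted p = 0.0163; adjusted p = 0.557 with an estimated correlation, and 0.0710 without sham replicate 2). Without the 4 arrays richest in atrial transcripts its mean was -1.29, with 2 members called lower and the list called (camera adjusted p = 0.0119), and with the atrial covariate it was 0.0017 (adjusted p = 0.886). Sln had a value of -5.47 ± 2.32 and Myl4 one of -5.03 ± 2.15 (SE), neither called (limma adjusted p = 0.231 and 0.238). Their 24 h means (5.04 and 4.81 log2) lay near background, so these values are no exact sizes. The levels of Sln and Myl4 split the arrays within groups. Myl4 lay between 13.49 and 16.16 log2 in sham replicates 2 and 3 and SAP 12 h replicates 3 and 4, between 4.66 and 8.49 in the other sham and 12 h arrays, and between 4.41 and 5.16 in the 24 h arrays. Adipoq, a fat cell hormone, was also highest in those 4 arrays (8.75 to 11.14 log2), whereas Myl2, the ventricular light chain, lay between 17.24 and 18.04 in all 15. With the mean of 6 atrial markers as a covariate, an alternative chosen after seeing the data, the mean of the fibroblast list at 24 h was -0.27 and that of the matrix list -0.31, and neither list was called (camera adjusted p = 0.152 and 0.129). Without the 4 arrays, chosen in the same way, the means were -0.49 and -0.43 and both lists were called (camera adjusted p = 0.00104 and 0.0107).

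**Figure D3:**
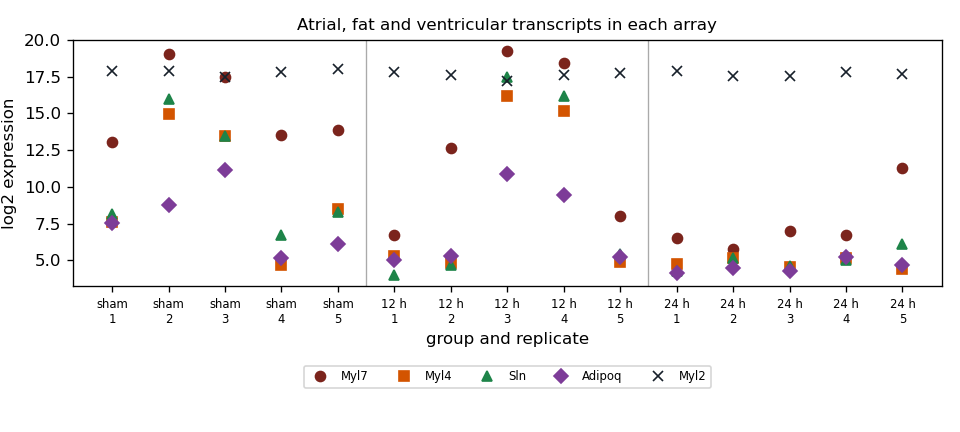
The log2 expression (y axis) of the atrial transcripts Myl7, Myl4 and Sln, the fat cell transcript Adipoq and the ventricular transcript Myl2 is shown for each of the 15 arrays (x axis, group and replicate number), 1 point per transcript and array. Myl7, Myl4, Sln and Adipoq are highest in sham replicates 2 and 3 and SAP 12 h replicates 3 and 4. Myl4 and Sln do not exceed 6.11 in the 24 h arrays, Myl7 reaches 11.30 in SAP 24 h replicate 5, and Myl2 stays between 17.24 and 18.04.

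In total 782 probe sets were called at 24 h, 286 higher and 496 lower, and 183 of them at least 2-fold. Fitted with only the compared groups the count was 1230, against 861 at 12 h, so the counts do not rank the time points. Repeated quantile normalization gave 364 higher and 435 lower, and median centring gave 248 and 539. Over all probe sets the groups did not overlap for 1390 (5.99%, against 0.794% by chance), of which 665 were called. The number of called probe sets fell to 480 (160 higher) without sham replicate 3, to 428 (171 and 168 higher) without sham replicate 5 or SAP 24 h replicate 2, and to 420 (160 higher) without SAP 24 h replicate 5. Without sham replicate 4 it was 526, of which 328 were lower. The count was 500 without the 4 arrays rich in atrial transcripts, of which 421 were also called with all arrays. Of the genes named for this comparison, the calls of Cpt1b, Ech1, Eci1, Hsph1 and Sgk1 were lost without these 4 arrays. With the atrial covariate those of Bgn, Col1a2, Cpt1b, Ctrb1, Ech1, Eci1, Kcnq1 and Sgk1 were lost. Camera called 16 of 44 lists, of which the glycolysis list alone kept a call with an estimated correlation, and fry called 2. Besides the oxidative stress and NRF2 list and the atrial list, the interferon, contractile, oxidative phosphorylation and endothelial lists lost theirs when 1 array was left out. Their camera adjusted p reached 0.415, 0.0557, 0.0726 and 0.0811 without sham replicates 2, 5 and 5 and SAP 24 h replicate 3.

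**Figure D4:**
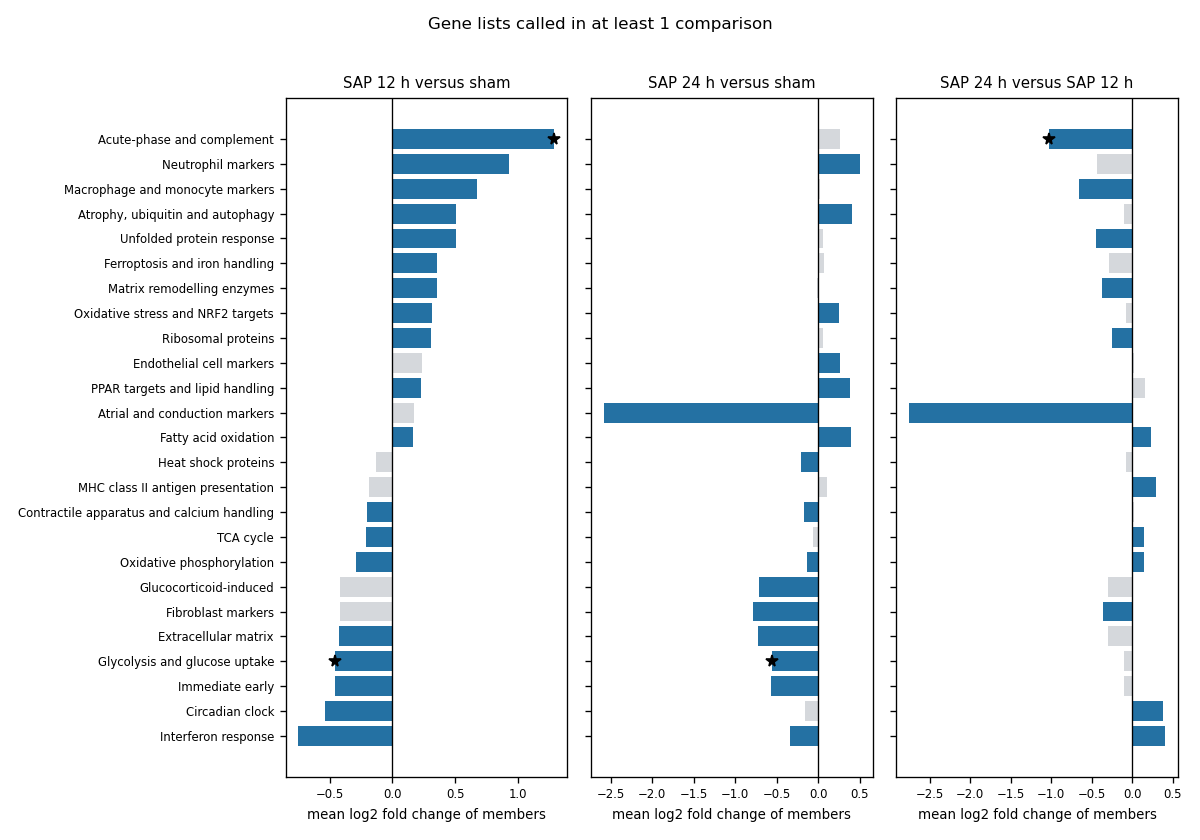
Bars show the mean log2 fold change of the measured members (x axis, with its own range in each panel) of the 25 gene lists called by camera in at least 1 comparison (y axis); blue bars are called in that comparison, grey bars are not, and a star marks a list that is also called with an estimated correlation. The acute-phase list is starred at 12 h and between the time points and the glycolysis list in both comparisons with sham.

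The third comparison set the 24 h hearts against the 12 h hearts. Timp1, a member of the acute-phase list, was 5.37-fold lower at 24 h than at 12 h (log2 fold change -2.43 ± 0.35 SE, adjusted p = 0.00203), the copper-binding Cp 4.97-fold (adjusted p up to 0.0914, without SAP 24 h replicate 2), Lbp 4.07-fold and the sulfhydryl oxidase Qsox1 3.6-fold. The clock gene Bmal1 was 3.76-fold lower. Dbp was 7.94-fold higher, Slc38a3 3.13-fold, Dgat2 3.09-fold, Nudt12 1.89-fold and Lgals9 1.86-fold (adjusted p up to 0.0967, without SAP 24 h replicate 4). In the acute-phase list, 11 of whose 19 members had been called higher at 12 h, 4 of 19 fell and none rose (12 when adjusted over the list alone; mean -1.02 log2, camera adjusted p = 7.11e-10, and 0.0414 with an estimated correlation). Of 15 macrophage and monocyte markers 4 fell and all 15 had negative values, with Cd14 at -1.56 and C1qb at -1.21 log2 (9 when adjusted over the list alone). The list had camera adjusted p = 6.14e-10, and adjusted p = 0.129 with an estimated correlation. In the unfolded protein response list 3 of 18 fell, including Dnajc3 (-1.11 log2), and none rose (12 fell and 2 rose when adjusted over the list alone). Camera gave adjusted p = 1.22e-06 for this list, but adjusted p = 0.168 with an estimated correlation. Of these macrophage markers 2 were called lower without the 4 arrays rich in atrial transcripts, and of the unfolded protein response list 1. The matrix protease Mmp14 fell by 1.71 log2, as 1 of 2 called members, with Timp1, of 16 matrix remodelling genes (2 when adjusted over the list alone). By camera the list had adjusted p = 0.0157, and adjusted p = 0.129 with an estimated correlation. Of 14 clock genes 2 rose and 3 fell, Clock by 1.22 log2 (7 and 3 when adjusted over the list alone), with camera adjusted p = 0.0239 for a net rise. The adjusted p of the clock list was 0.0930 without SAP 12 h replicate 5, and adjusted p = 0.618 with an estimated correlation. All 19 fatty acid oxidation genes had positive values, limma called none over all probe sets, 4 had an unadjusted p under 0.05 and 4 rose when adjusted over the list alone. For this list camera adjusted p was 2.23e-04, but adjusted p = 0.618 with an estimated correlation. The 18 ribosomal protein genes were all negative, with Rpl3 called (-1.04 log2; adjusted p up to 0.108, without SAP 24 h replicate 2) and 2 called when adjusted over the list alone (list camera adjusted p = 2.17e-05; adjusted p = 0.618 with an estimated correlation). The 9 atrial and conduction markers were all negative with a mean of -2.75 log2. Limma called none of them, and 2 had an unadjusted p under 0.05 (list camera adjusted p = 0.00106; adjusted p = 0.522 with an estimated correlation and 0.730 without the 4 arrays rich in atrial transcripts).

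Between the time points 160 probe sets were called, 28 higher and 132 lower at 24 h, 72 of them at least 2-fold. This count ranged from 73 (9 higher, 64 lower) without SAP 24 h replicate 2 to 398 (130 higher, 268 lower) without SAP 12 h replicate 2. It was 90 (13 higher) without SAP 12 h replicate 4, and 78, 80 and 95 (9, 12 and 11 higher) without SAP 24 h replicates 1, 4 and 5. Without SAP 12 h replicate 1 it was 148, of which 18 were higher. Repeated quantile normalization gave 53 higher and 105 lower, array weights gave 47 and 161, and leaving out the lowest 50% of probe sets gave 45 and 188. The count was 85 without the 4 arrays rich in atrial transcripts, of which 56 were also called with all arrays. Of the genes named for this comparison, the calls of Chi3l1, Ciart, Cp, Enpp3, Hsph1, Lgals9, Mgst1, Npas2, Nudt12, Pdia4, Qsox1 and Rpl3 were lost without these 4 arrays. With the atrial covariate those of Ciart, Cp, Enpp3, Hsph1, Lgals9, Mgst1, Npas2, Pdia4, Qsox1 and Rpl3 were lost. Camera called 13 of 44 lists, of which the acute-phase list alone kept a call with an estimated correlation, and fry called 5. Besides the clock list, 5 lists lost the call with 1 array left out, with these highest adjusted p: interferon response (0.277 without SAP 24 h replicate 4), TCA cycle (0.127 without SAP 12 h replicate 3) and oxidative phosphorylation (0.0501 without SAP 12 h replicate 3), and further MHC class II antigen presentation (0.0930 without SAP 12 h replicate 5) and fibroblast markers (0.529 without SAP 12 h replicate 3). A total of 20 of 100 splits of these arrays, the real one included, called at least 13 lists. Against sham, 397 probe sets were called at both times in the same direction, 134 higher and 263 lower, and none in opposite directions. The overlap was 225 without sham replicate 5, 244 without the 4 arrays rich in atrial transcripts, 255 without SAP 24 h replicate 2 and 244 without SAP 24 h replicate 5. Independent lists of the same sizes would share 6.71 higher and 12.7 lower probe sets, and 100 simulations of unchanged groups against the same sham arrays shared 0. That 0 is what no change gives, and it does not measure what the shared controls add to the overlap. Because both comparisons used the same 5 sham arrays, the sham group was also split 20 ways so that each comparison had its own controls, and 41 to 116 probe sets were then shared (median 99.5). With only 2 or 3 controls each, the comparisons themselves called fewer probe sets (medians of 489 at 12 h and 253 at 24 h), so the lower overlap is not the part due to shared controls. The log2 fold changes at 12 h and 24 h correlated across probe sets with r = 0.606, but with 0.502 on average when all groups were simulated without change, where the comparisons share the sham arrays (0.402 as the median over the split controls; probe sets are not independent replicates). Their covariance was 0.0591 against 0.0175 when all groups were simulated without change. A further 743 probe sets were called at 12 h but not at 24 h and 385 at 24 h but not at 12 h, and 107 and 19 of these also differed between the time points.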

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

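The tests of explanations and the splits of the arrays in this part were set up after the results they bear on had been seen, whereas the test of 24 h against 12 h was not.

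Atrial transcripts differed widely between arrays of 1 group and matrix and fibroblast lists were lower at 24 h, when Myl4 and Sln lay at most at 5.16 and 6.11 log2, but Nppa reached 16.89 in SAP 24 h replicate 4 and Myl7 11.30 in replicate 5. Different shares of atrial tissue among the arrays are a candidate explanation that these values leave open for the 24 h difference. Of the 4 atrial markers not used to choose the arrays, 2 (Nppa and Myl7) had the same 4 highest arrays as Myl4 and Sln. Of these arrays 2 were sham and 2 SAP 12 h, so the treatment group does not account for the split within these groups. Bmp10 and Stard10 did not have the same 4 highest arrays. They were highest in sham replicate 2 and SAP 12 h replicates 3 and 4 (9.72 to 16.09 and 11.59 to 13.51 log2). In sham replicate 3 they lay at 3.88 and 8.94, and in the remaining arrays at most at 4.44 and 8.97. With the atrial score as a covariate 35.0% of the fibroblast list's mean log2 fold change at 24 h was left, so part of the fibroblast and matrix values may belong to what was dissected, though the score differs between the groups and can also take up a true difference. Without the 4 arrays the fibroblast list kept a mean of -0.49 against -0.78 with all arrays and camera called it (adjusted p = 0.00104), but with all arrays it had adjusted p = 0.557 with an estimated correlation and 0.173 with fry, so whether these 4 arrays are the whole cause stays open. Without them the atrial list also stayed lower at 24 h, with a mean of -1.29 against -2.58 log2 (camera adjusted p = 0.0119). With all arrays the atrial list had camera adjusted p = 0.557 with an estimated correlation. A fall of Myl4 and Sln in heart muscle itself by 24 h of SAP cannot be told apart from different shares of atrial tissue. For Myl4 the lowest sham array lay at -0.50 log2 relative to the highest 24 h array, but it was only 1 of 5. All 5 sham arrays lay above all 24 h arrays for Sln (lowest 6.70, highest 6.11) and for Myl7.

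The clock genes at 12 h moved by arm, with activators higher and output genes lower. Collection at another time of day than the sham hearts cannot be told apart from a response to SAP that passes within a day, since no clock hour is given for any group. That 11 of 12 measured genes had values in the direction of their arm, called or not, restates the pattern and is no separate support (Nr1d1 at 0.22 log2 was the exception, and Cry1 and Cry2 at -0.23 and -0.46 were not counted). The 8 clock genes called at 12 h kept 17.4% of their mean absolute log2 fold change at 24 h. For 5 of them, Bmal1, Clock, Npas2, Dbp and Ciart, the 95% interval at 24 h excluded 50% of the 12 h value. In these 5 genes a 24 h difference from sham of that size is therefore not there. They were picked by this interval, so that all 5 pass is no separate test. A lasting change of the clock after SAP cannot be decided by it either, since the sham and 24 h hearts may differ in clock hour. Of Per2, Per3 and Tef 0 had such an interval (-0.92 to -0.08, -1.18 to -0.15 and -1.31 to -0.06). A lasting difference from sham cannot be told apart from a return for these genes. They were called neither against sham at 24 h nor between the time points.

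Neutrophil-type transcripts rose at 12 h. More blood left in the 12 h hearts would raise the haemoglobin genes as well, but the upper 95% bound of the Hba-a1 log2 fold change was 0.85, and those of Hbb and Hbb-b1 were 0.71 and 0.94, below the rises of S100a9 (3.20) and S100a8 (2.67). Neutrophils in the tissue may contribute, but the median log2 fold change of the 9 other neutrophil markers was 0.16, and only 1 of them had a sham mean above 6 log2, so this cannot be told apart from expression by other cells. A higher share of white cells in the blood was not tested.

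Every other split into 5 and 5 arrays keeps 3 or 4 arrays of each group together, so its count holds part of the real contrast. Mixing the groups also widens the spread on each side of the split, which can lower its count. None of the 99 other splits drawn per comparison reached the real count of called probe sets. It was 1140 against at most 16 at 12 h, 782 against at most 7 at 24 h and 160 against at most 9 between the time points. In each comparison only 1 of the 100 splits gave as many, the lowest share that these splits can give. Chance is therefore unlikely for these counts, but 100 splits cannot exclude it. For gene lists the real groups gave 19 against at most 17 at 12 h and 16 against at most 13 at 24 h, again 1 of 100 splits each. The other splits called 9 and 6 lists as a median. Leaving out 1 array took the real counts as low as 16 and 13, and with an estimated correlation camera called 2 and 1. Chance is therefore unlikely for these 2 numbers of lists, but the margin is too thin to exclude it. Between the time points 20 of 100 splits called at least the real 13 lists, with a highest of 18, so there chance cannot be excluded for the number of lists by these mixed splits.

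A total of 18 of 291 sets of 5 arrays, over the 97 genes named, had 1 array far from the other 4, where chance gives about 14.55. In log2 these were Fgg in SAP 24 h replicate 3 (9.0, others 5.89 to 6.76), Mgst1 in SAP 12 h replicate 5 (12.73, others 13.21 to 13.37), Slc38a3 in SAP 24 h replicate 4 (10.75, others 11.54 to 11.78), Fcer2 in sham replicate 2 (5.35, others 7.26 to 7.95), Ncf1 in sham replicate 2 (9.25, others 10.83 to 11.23) and Trim16 in SAP 12 h replicate 1 (7.83, others 5.79 to 6.34). Further ones were Timp1 in sham replicate 3 (7.87, others 6.29 to 6.51), Clock in SAP 24 h replicate 1 (10.18, others 10.94 to 11.23), Cyc1 in SAP 12 h replicate 3 (14.79, others 15.22 to 15.28), Pgam2 in sham replicate 4 (15.21, others 14.71 to 14.84), Myl7 in SAP 24 h replicate 5 (11.30, others 5.75 to 7.03) and Hk2 in SAP 12 h replicate 2 (10.55, others 8.16 to 8.66). The remaining ones were Egr1 in SAP 12 h replicate 2 (10.37, others 9.74 to 9.89), Cpt1b in SAP 24 h replicate 4 (15.84, others 16.06 to 16.13), Ech1 in SAP 12 h replicate 2 (16.13, others 17.42 to 17.75), Nudt12 in sham replicate 3 (8.75, others 9.02 to 9.13), Lipe in SAP 24 h replicate 4 (9.0, others 9.46 to 9.62) and Fga in SAP 24 h replicate 3 (5.98, others 4.95 to 5.14).

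Expression differed between the time points, by limma's test of 24 h against 12 h, for 20 genes named in the comparisons with sham. The same sham arrays served both times and no hour of day is given. A difference in the response to SAP therefore cannot be told apart from time of day or time after surgery. Log2 values were lower at 24 h than at 12 h for Chi3l1 (-2.87), Mgst1 (-1.05), Enpp3 (-1.62), Ifitm1 (-1.39), Lbp (-2.03), Osmr (-0.65), Timp1 (-2.43), Bmal1 (-1.91), Clock (-1.22), Dnajc3 (-1.11), Pdia4 (-1.36), C1qb (-1.21), Hsph1 (-0.73), Gja1 (-0.98), Grk5 (-1.09), Npas2 (-1.04), and higher for Dbp (2.99), Slc38a3 (1.65), Dgat2 (1.63), Ciart (1.61). Of the 15 fits that each left out 1 array, some ended the call, with these highest adjusted p: Osmr (12 fits, up to 0.119 without SAP 24 h replicate 1), Npas2 (10 fits, up to 0.113 without SAP 24 h replicate 1), Pdia4 (7 fits, up to 0.0983 without SAP 24 h replicate 2), Mgst1 (7 fits, up to 0.0853 without SAP 24 h replicate 1), Enpp3 (3 fits, up to 0.0596 without SAP 24 h replicate 2), Gja1 (1 fit, up to 0.0548 without SAP 24 h replicate 2), Ciart (1 fit, up to 0.0529 without SAP 24 h replicate 1) and Hsph1 (1 fit, up to 0.0502 without SAP 24 h replicate 1). The atrial covariate ended the calls of Ciart, Enpp3, Hsph1, Mgst1, Npas2 and Pdia4, and the fit without the 4 arrays those of Chi3l1, Ciart, Enpp3, Hsph1, Mgst1, Npas2 and Pdia4. By camera 13 lists differed. Mean log2 differences were negative for these lists: Acute-phase and complement (-1.02), Unfolded protein response (-0.45), Matrix remodelling enzymes (-0.37), Ribosomal proteins (-0.25), Macrophage and monocyte markers (-0.66), Fibroblast markers (-0.36), Atrial and conduction markers (-2.75). They were positive for these: Interferon response (0.41), Circadian clock (0.38), Fatty acid oxidation (0.23), TCA cycle (0.15), Oxidative phosphorylation (0.15), MHC class II antigen presentation (0.29). With an estimated correlation only the acute-phase list kept its call. The mean of the fibroblast list was positive with the atrial covariate and without the 4 arrays (0.17 and 0.15 log2, camera adjusted p = 0.419 and 0.356). In these 2 fits the calls also ended for the atrial list (0.826 and 0.730), the TCA cycle list (0.198 and 0.312), the oxidative phosphorylation list (0.162 and 0.0756) and the MHC class II list (0.0723 and 0.0591). The interferon list lost its call without the 4 arrays (0.104).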

How the results depend on the processing

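The fit with the atrial covariate and the fit without the 4 arrays with high atrial markers were chosen after seeing the data. The second deposited table was identical, so it was not run as an alternative. Of 134 calls of named genes, 109 were kept under every alternative fixed in advance, 116 with the atrial covariate and 106 without the 4 arrays, and 0 reversed under any of these. Of 48 list calls, 36 were kept with the atrial covariate, 33 without the 4 arrays, 29 in every fit that left out 1 array, 4 with camera's estimated correlation, 17 with fry and 32 with the lowest 50% of probe sets left out.

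Probe set counts moved by over 1.5 times as follows, in the order 12 h against sham, 24 h against sham and 24 h against 12 h where all 3 moved. A 2-fold minimum left 327, 183 and 72, and adjusted p under 0.01 left 507, 255 and 40, as stricter rules must. Without the 4 arrays the counts were 598, 500 and 85, of which 508, 421 and 56 were shared with all arrays, and 244 were called at both times in the same direction. With the atrial covariate 24 h against sham gave 503 (424 shared) and 24 h against 12 h gave 83 (64 shared). For 12 h against sham it gave 1241 (1109 shared), which is not a move of that size. Fitting only the compared groups gave 1230 for 24 h against sham and 75 for 24 h against 12 h, and array weights gave 1263 for 24 h against sham. For 12 h against sham these settings gave 861 and 1179, so the order of the main counts (1140 at 12 h, 782 at 24 h) reversed. The median spread within a group was largest at 12 h (0.245 log2, against 0.210 in sham and 0.212 at 24 h). The cause was not tested. Repeated quantile normalization split the 24 h against 12 h calls into 53 higher and 105 lower, against 28 and 132.

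The number of lists called fell to 11 at 12 h and 10 at 24 h with the lowest 50% of probe sets left out (fewer members tested), to 2, 1 and 1 with an estimated correlation, and with fry, which tests another hypothesis, to 2 at 24 h and 5 between the time points. At 24 h the atrial list reversed to a rise with the atrial covariate (adjusted p = 0.886), as its construction implies. The fibroblast list of 24 h against 12 h reversed with it (adjusted p = 0.419) and without the 4 arrays (adjusted p = 0.356). The atrial list at 12 h turned to a called fall without the 4 arrays (adjusted p = 0.0426).

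Leaving out each array in turn gave 786 to 1202 probe sets at 12 h, 420 to 1001 at 24 h and 73 to 398 between the time points. It gave 225 to 459 called at both times, and 16 to 20, 13 to 16 and 10 to 16 lists.

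The replicate numbers do not pair the samples: of 15 same-number pairs 2 had a correlation of deviations over 0.1 (range -0.17 to 0.26), and 2 of 15 arrays matched best with their own number. With the replicate number as a block the counts were 1030, 657 and 162 probe sets, 20, 16 and 14 lists, and 343 called at both times.

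The calls of named genes and of lists ended by the settings below were as follows. Leaving out the lowest 25% of probe sets ended those of Fatty acid oxidation list (12 h), Fibroblast markers list (24 h against 12 h), Immediate early list (12 h), Matrix remodelling enzymes list (12 h), MHC class II antigen presentation list (24 h against 12 h) and PPAR targets and lipid handling list (12 h). Repeated quantile normalization ended those of Col1a2 (24 h), Npas2 (24 h against 12 h), Osmr (24 h against 12 h), Rpl3 (24 h against 12 h), Sgk1 (24 h), Fatty acid oxidation list (12 h), Immediate early list (12 h), Matrix remodelling enzymes list (12 h), Oxidative stress and NRF2 targets list (12 h) and PPAR targets and lipid handling list (12 h). The atrial covariate ended those of Bgn (24 h), Ciart (24 h against 12 h), Col1a2 (24 h), Cp (24 h against 12 h), Cpt1b (24 h), Ctrb1 (24 h), Ech1 (24 h), Eci1 (24 h), Enpp3 (24 h against 12 h), Hsph1 (24 h against 12 h), Kcnq1 (24 h), Lgals9 (24 h against 12 h), Mgst1 (24 h against 12 h), Npas2 (24 h against 12 h), Pdia4 (24 h against 12 h), Qsox1 (24 h against 12 h), Rpl3 (24 h against 12 h), Sgk1 (24 h), Atrial and conduction markers list (24 h against 12 h), Endothelial cell markers list (24 h), Extracellular matrix list (24 h), Fatty acid oxidation list (12 h), Fibroblast markers list (24 h), MHC class II antigen presentation list (24 h against 12 h), Oxidative phosphorylation list (24 h against 12 h), Oxidative stress and NRF2 targets list (24 h), PPAR targets and lipid handling list (12 h) and TCA cycle list (24 h against 12 h). The fit without the 4 arrays ended the list calls of Atrial and conduction markers list (24 h against 12 h), Fatty acid oxidation list (12 h), Ferroptosis and iron handling list (12 h), Heat shock proteins list (24 h), Immediate early list (12 h), Interferon response list (24 h against 12 h), Interferon response list (24 h), Matrix remodelling enzymes list (12 h), MHC class II antigen presentation list (24 h against 12 h), Oxidative phosphorylation list (24 h against 12 h), Oxidative stress and NRF2 targets list (24 h), PPAR targets and lipid handling list (12 h), Ribosomal proteins list (12 h) and TCA cycle list (24 h against 12 h). Centring ended those of Npas2 (24 h against 12 h), Osmr (24 h against 12 h) and Immediate early list (12 h). Trend and robust settings ended those of Atf3 (12 h), Bgn (24 h), Col1a2 (24 h), Cp (24 h against 12 h), Myl7 (24 h), Serpina3n (12 h), Sgk1 (24 h) and Trim16 (12 h). Fitting only the compared groups ended those of Ciart (24 h against 12 h), Cp (24 h against 12 h), Gja1 (24 h against 12 h), Hsph1 (24 h against 12 h), Kcnq1 (12 h), Mgst1 (24 h against 12 h), Npas2 (24 h against 12 h), Osmr (24 h against 12 h), Pdia4 (24 h against 12 h), Rpl3 (24 h against 12 h), Rps6 (12 h) and Fatty acid oxidation list (12 h), and the replicate block those of Cpt1b (24 h), Lgals9 (24 h against 12 h), Osmr (24 h against 12 h), Sgk1 (24 h), Trim16 (12 h), Circadian clock list (24 h against 12 h) and PPAR targets and lipid handling list (12 h).

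Signal over background limits the low genes: the median level of all probe sets was 5.93 log2, against a median of 4.65 for the pancreatic acinar genes.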

Other observations

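The test on fasting-response genes and the choice of the genes given here came after their values were seen, and the test on Slc30a1 did not. Genes of lists that camera did not call also differed from sham. Among cardiac ion channel and gap junction genes the pacemaker channel Hcn2 fell by 1.69 log2 at 12 h (limma adjusted p = 0.00107) and had -1.10 at 24 h (adjusted p = 0.0319, but 0.0865 without sham replicate 5). The potassium channel Kcnq1 fell by 0.90 log2 at 24 h (adjusted p = 0.0124) and by 0.78 at 12 h (adjusted p = 0.0210, but 0.0602 without SAP 12 h replicate 1). The 24 h call was lost with the atrial covariate and the 12 h call without the 4 arrays rich in atrial transcripts, both chosen after seeing the data. Gja1, the main ventricular gap junction protein, rose by 1.32 log2 at 12 h (adjusted p = 3.05e-04), and its 24 h value relative to 12 h was -0.98 (adjusted p = 0.0148, but 0.0548 without SAP 24 h replicate 2). The receptor kinase Grk5 rose by 1.35 log2 at 12 h (adjusted p = 9.29e-05) and fell by 1.09 from 12 h to 24 h. Prkaca, a catalytic subunit of protein kinase A, fell by 0.61 log2 at 12 h and fell by 0.58 at 24 h (adjusted p = 0.00459 and 0.0104). Lipe, the hormone-sensitive lipase, rose by 1.13 log2 at 12 h and 1.35 at 24 h (adjusted p = 0.00554 and 0.00247).

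The 8 lung and airway genes had a median level of 4.47 log2, the 13 pancreatic acinar genes 4.65 and the 11 hepatocyte genes 4.62. The highest mean levels in these lists were those of Hopx (11.74), Amy2a3 (7.13) and Ttr (10.73). In the acinar list Ctrb1, a chymotrypsinogen, with a low mean level of 4.39, was 0.77 log2 higher at 24 h (adjusted p = 0.0253, but 0.0682 without sham replicate 4). This call was lost with the atrial covariate, and camera did not call the list (adjusted p = 0.101). In the hepatocyte list the fibrinogen chains Fga (0.93 log2, mean level 5.43) and Fgg (2.97) rose at 12 h, and the Fga call was lost without the 4 arrays rich in atrial transcripts.

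A lower activity of the zinc sensor that drives the metallothionein genes may lie behind the lower Mt1 and Mt2A. Slc30a1, another target of that sensor, had a log2 fold change of 0.026 at 24 h (95% interval -0.23 to 0.28) and -0.32 at 12 h (-0.57 to -0.07, adjusted p = 0.164), so a fall of the size seen in Mt1 is not there, but the 12 h interval leaves a smaller one open. A fasting-like response through PPAR alpha may lie behind the higher fatty acid oxidation list at 24 h. The 4 measured fasting-response genes had a median log2 fold change of 0.79, with Pdk4 at 1.40 and Angptl4 at 1.28 (adjusted p = 0.0824 and 0.0907), Cpt1a at 0.30 and Ucp3 at -0.18. Limma called 0 of them, so the values leave it open. Food intake is not given in the sources used here.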
